A study of Mus musculus with 24 samples.

How the data were processed

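The labels give total RNA as the molecule. RNA was extracted with a Qiagen RNeasy kit and libraries were made with a NEBNext Ultra RNA kit, per the labels' protocols. The submitters' processing notes name CASAVA, STAR and the mouse build mm10, with no versions; the counting tool and its strand setting are not given in the sources used here, so a gene and an overlapping or antisense neighbour may share reads. The deposited table of the whole series gives FPKM, read counts scaled by the listed gene length and by the reads assigned to genes in the library, for 35275 genes in 24 libraries, per the file headers. The deposited comparison tables give, per the file headers, read counts of the libraries, the authors' group means as a size-factor-scaled signal, the authors' log2 fold change and the authors' p-value and adjusted p-value, for the genes listed as changed only.

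Libraries were assigned to groups by name. A first letter f was read as floxed control, and z as knockout, because the authors' knockout mean column in each comparison table is a weighted mean of the z columns. A name ending in e was read as epididymal, the gonadal pad of male mice, and one ending in s as subcutaneous, the inguinal pad. The replicate numbers of the labels do not occur in the names, so columns were mapped to groups, not to individual samples. The names carry 6 animal numbers (M5, M9 and M12 knockout; M6, M7 and M10 control), each with 2 libraries per pad. The 12 pairs of libraries from a pad correlated at r = 0.991 to 0.996 across genes, with chi-square per degree of freedom of 2.09 to 15.6, above sampling noise, while 48 pairs from different mice of a group correlated at 0.897 to 0.985, with chi-square per degree of freedom of 18.2 to 143.

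The design fixed before the data were examined counted the 6 libraries of a group as replicates. After the names and these correlations were seen, the mouse was made the replicate: the FPKM of the 2 libraries of a pad were averaged and each fit compared 3 mice with 3. This departs from the design as fixed, and the fit as fixed is reported beside the main counts. On simulated data with no gene changed, the 6-library fit called 392 gonadal genes of 14851 and 284 inguinal genes of 13621, and the 3-mouse fit called 0 and 1. Each gene had its measured variation between mice but was drawn independently of other genes, so variation shared by the genes of a pad was absent. On the real data, splits mixing the genotypes called up to 2871 gonadal and 4216 inguinal genes with the 6-library fit. The 3-mouse fit called up to 45 gonadal genes in such splits. What the names mean was inferred, and whether the 2 libraries of a pad are repeat preparations or separate pieces of tissue is not given in the sources used here.

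Genes with a mean FPKM of at least 0.5 over the mice in a fit were tested with limma 3.58.1 in R 4.3.3 (trend, two-sided) on log2(FPKM + 0.5), with Benjamini-Hochberg adjusted p under 0.05 as the threshold. Fold changes are on that scale and understate the change of low genes. Each knockout comparison used its own depot, the interaction used all 12 pads in 4 groups, and the depot comparison used control mice. Foxo1 was also tested with an exact permutation test over the 20 regroupings of 6 mice. Tested on simulated data with 200 genes changed, the 3-mouse fit recovered 57% of 2-fold and 93% of 4-fold changes in the gonadal comparison (14851 genes) and 62% and 89% in the inguinal one (13621 genes), with 11 and 5 unchanged genes called. Genes were drawn independently there too, and the changed genes were taken above a minimum control level.

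The 41 gene lists, of pathways and of cell types that a pad or its dissection could hold, were fixed before the data were examined; 696 of 699 list genes were found, 3 of them under another symbol. Lists with at least 3 tested members were tested with camera at a preset correlation of 0.01, adjusted over all lists, and again with an estimated correlation and with fry. Counts of members that rose or fell are given over all genes and adjusted over the list alone. Named genes are Foxo1, the 10 genes with the largest change each way among those past the threshold with a mean of at least 1 FPKM in a group, without unnamed models and pseudogenes (where none passed, the 10 with the smallest p), and up to 4 members with the smallest p of each list described. For the interaction and the depot comparison, 5 genes each way and the depot developmental genes were taken. A gene the rule takes in the depot comparison is not reported here. Gm12725, Nnat in gonadal fat, Retn, and the B cell, muscle, epididymal and haemoglobin genes given per pad were named after their values were seen.

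Multiplying FPKM by gene length and library total gave whole reads for 100% of values (tolerance 0.001). The library totals came from genes with at least 50 reads in the comparison tables. The rebuilt read counts, summed per mouse and pad, were tested with edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 as added alternatives, since the deposited unit of the full table is FPKM. The libraries held 14953657 to 25438811 reads. SD values are the spread between 3 mice, which includes counting error. The SE of a log2 difference is limma's moderated standard error, which also borrows variance from the other genes. Where equal animal numbers mark the pads of a mouse, deviations from the group means correlated across depots at -0.10 to 0.14. The blocked fits use that number.

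Alternatives fixed before the data were examined were pseudocounts of 0.1 and 1, no filter and a mean of at least 2 FPKM, median-ratio scaling, quantile normalization, array weights, a robust trend, all groups in a joint fit, leaving out each mouse, and the list test variants. Those chosen after seeing the data were the 6-library fit, edgeR, DESeq2, the animal number as a block, male tract, B cell and muscle lists as covariates, and fits without pads that held or lacked neighbouring tissue. Gene identifiers were compared with GENCODE M21, where 99.8% of shared identifiers overlapped the same place. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 prepared tables and figures.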

Results

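RNA was sequenced from the gonadal and inguinal white fat pads of mice lacking FoxO1 in adipose tissue and of mice carrying the floxed, unrecombined gene, which served as controls. FoxO1 is a transcription factor that insulin signalling keeps out of the nucleus, and the stated purpose of the series was to find the genes and pathways it regulates. The deposited values covered 24 libraries in 4 groups of 6. The library names gave 6 mice, 3 knockout and 3 control, each with 2 libraries from each pad. Each of the 24 libraries resembled the other library of its own pad more closely than any library of another mouse. The mouse was therefore taken as the replicate (n = 3 per group), with its 2 libraries averaged. Counts from a fit that treats all 6 libraries of a group as replicates are given beside the main counts. The libraries held 14953657 to 25438811 reads assigned to genes.

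Foxo1, the targeted gene, was lower in every knockout pad than in any control pad of the same depot. In gonadal fat it stood at 4.18 ± 0.24 FPKM in knockout mice and 10.3 ± 2.9 FPKM in controls (SD, n = 3), which is 40.5% of the control level. In inguinal fat the values were 4.10 ± 1.60 and 15.7 ± 3.5 FPKM (SD, n = 3), or 26.1% of control. The gene (ENSMUSG00000044167) lies on the plus strand of chromosome 3 at 52268337 to 52350109 in mm10. Its value is a total over the whole gene in a whole pad. Which exons are deleted is not given in the sources used here, so reads from exons that remain can be part of it, as can transcripts from cells that keep the gene. The log2 fold change was -1.18 (SE 0.19) in gonadal and -1.86 (SE 0.29) in inguinal fat. The exact two-sided permutation test gave p = 0.1 in each depot, the smallest that 3 mice against 3 allow. The limma adjusted p was 0.407 in gonadal and 0.129 in inguinal fat. In the authors' deposited tables, Foxo1 had log2 fold changes of -1.16 in gonadal and -1.61 in inguinal fat. The sister factors Foxo3 and Foxo4 differed by -0.03 (SE 0.14) and -0.12 (SE 0.13) in gonadal fat. In inguinal fat they differed by -0.35 (SE 0.19) and -0.13 (SE 0.08), with limma adjusted p of 0.451 or more.

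**Figure D1:**
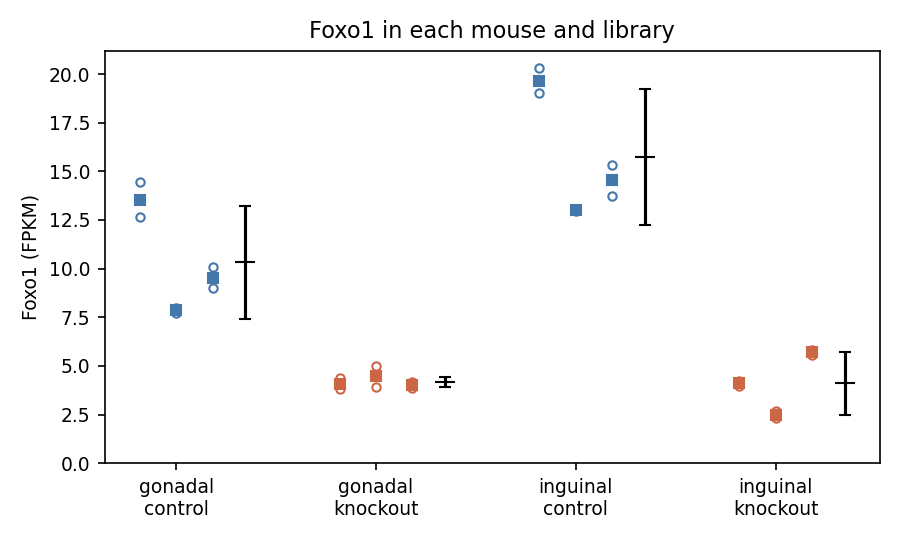
Foxo1 level (FPKM, linear axis from 0) in each group of 3 mice. Open circles are libraries, filled squares are the mean of a mouse's 2 libraries, and bars at the right of each group show mean ± SD over mice; knockout mice sit between 2.49 and 5.69 FPKM and control mice between 7.87 and 19.7 FPKM.

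Gonadal fat of knockout mice was higher than control in genes of fat synthesis and storage and lower in interferon-stimulated and red blood cell genes. The lists were tested with limma camera at a preset correlation, and each adjusted p with an estimated correlation, which no list passed, is given beside it. That variant called 0 lists in every comparison. Between the depots of control mice it gave adjusted p = 0.345 for oxidative phosphorylation, where all 34 members were called singly. Not passing it therefore does not separate changed from unchanged lists. Fry's directional test called 27 of 41 lists between those depots, but 0 in either knockout comparison. At the preset correlation, splits mixing the genotypes called up to 21 gonadal and 20 inguinal lists, against 19 in each depot for the genotypes. De novo lipogenesis genes rose (17 of 21 members higher, median log2 fold change 0.68). Their camera adjusted p was 9.38e-10, and adjusted p = 0.578 with an estimated correlation. Fasn, the fatty acid synthase, was 413 FPKM in knockout and 138 FPKM in control pads (log2 fold change 1.52, SE 0.32), and the desaturase gene Scd1 differed by 1.53 (SE 0.34). Me1, which encodes malic enzyme, differed by 1.39 (SE 0.29) and Pnpla3 by 1.25 (SE 0.25). Adjusted over the list alone, 11 lipogenic members rose and 0 fell, and over all genes tested 0 passed. The list mean of 2 of the 3 knockout pads lay above all controls, with knockout mouse M5 at 5.76 and control mouse M6 at 5.77. Setting M5, M7 and M10 against the other mice, which mixes the genotypes, gave a larger absolute median of 0.77. That split only exchanged M5 for M6, with M9 and M12 still set against M7 and M10. It therefore retained part of any genotype effect.

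Lipolysis and triglyceride storage genes rose in gonadal fat as well (21 of 23 members higher, median 0.47, camera adjusted p = 6.03e-14, adjusted p = 0.578 with an estimated correlation). Of them 14 passed when adjusted over the list alone. Pck1, the glyceroneogenic enzyme, was 220 ± 25 FPKM in knockout and 94.0 ± 14.0 FPKM in control pads (SD, n = 3). Dgat1, Agpat2 and Lpl differed by 0.68 (SE 0.10), 1.56 (SE 0.27) and 0.85 (SE 0.17). All 34 oxidative phosphorylation genes were higher, by a small median of 0.27 (camera adjusted p = 2.95e-20, adjusted p = 0.578 with an estimated correlation). Cyc1 stood at 0.42 (SE 0.09), and 0 members passed when adjusted over the list alone. Fatty acid oxidation genes (19 of 19 members higher, median 0.31) and branched-chain amino acid breakdown genes (19 of 20, median 0.33) also rose. Their camera adjusted p was 5.13e-13 and 5.58e-11, each with adjusted p = 0.578 with an estimated correlation. Adjusted over the list alone, 7 and 4 of their members passed, including Cpt2 (0.60, SE 0.11) and Bcat2 (0.56, SE 0.11). The adipocyte identity list rose (19 of 23 members higher, median 0.46, camera adjusted p = 5.34e-07, adjusted p = 0.578 with an estimated correlation). In it 9 members rose and 2 fell when adjusted over the list alone. Acsl1 and Nrg4 were higher by 1.04 (SE 0.19) and 0.95 (SE 0.20), while Nnat, the imprinted gene encoding neuronatin, was lower at -1.60 (SE 0.43).

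Interferon-stimulated genes fell in gonadal fat, with all 20 members lower (median -0.77, camera adjusted p = 4.42e-10, adjusted p = 0.578 with an estimated correlation). Isg15 was 11.9 FPKM in knockout and 39.9 FPKM in control pads, and Rsad2 and Ifit1 differed by -1.44 (SE 0.46) and -1.19 (SE 0.41). However, 0 members passed when adjusted over the list alone. Control mouse M6 stood apart: its list mean was 3.76 on the log2 scale, against 2.68 and 2.85 in the other controls. Without M6 the median was -0.44 and the list was still called. In the pads with no epididymal transcripts, which include 1 control mouse and therefore rest on it, the median was -0.30. Red blood cell genes were all lower too (7 of 7, median -1.57, camera adjusted p = 4.89e-06, adjusted p = 0.578 with an estimated correlation). Of these, 5 passed when adjusted over the list alone, Slc4a1 among them, and the median was -0.88 in those pads with 1 control mouse. Extracellular matrix genes fell less (23 of 26 members lower, median -0.31, camera adjusted p = 1.86e-04, adjusted p = 0.578 with an estimated correlation). Postn, which encodes periostin, was the member that passed when adjusted over the list alone (-0.60, SE 0.08). Of the 41 lists, 19 were called in gonadal fat, 9 higher and 10 lower. The other calls were mitochondrial dynamics, thermogenic and circadian genes upward, with T and NK cell, progenitor, inflammatory, immediate early, B cell, endoplasmic reticulum stress and neutrophil genes downward. Their adjusted p with an estimated correlation lay between 0.578 and 0.764. Without knockout mouse M12, 7 of the 19 list calls were lost. They were inflammatory (median -0.082), immediate early (-0.080), neutrophil (-0.165), B cell (-0.184), progenitor (-0.195), extracellular matrix (-0.196) and circadian genes (0.099). The gonadal pad of M12 held 8 male tract genes above 100 FPKM, the most of any pad. The T and NK cell median was -0.06 in the pads with no epididymal transcripts, a value that rests on 1 control mouse.

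No gene reached an adjusted p under 0.05 in gonadal fat (limma, 14851 genes tested), while 1291 genes had an unadjusted p under 0.05. Of the other 9 splits of the mice, all mixing the genotypes, the highest gave 2330 such genes and the next 1536. On rebuilt read counts, edgeR called 0 genes and DESeq2 308. With the 6 libraries of a group counted as replicates, 569 genes were called higher and 556 lower, and the authors' deposited table lists 990 higher and 818 lower. The genes with the smallest p had limma adjusted p from 0.395 to 0.407. They were Gsta3, a glutathione transferase (0.97, SE 0.10), Rfc4 (0.83, SE 0.09), Pck1 (1.23, SE 0.14), Cldn22 (1.41, SE 0.17) and Bcl6 (-0.82, SE 0.10). Next came Frzb (-1.17, SE 0.14), Bcar3 (1.15, SE 0.15), Hsd11b1 (0.92, SE 0.12), Mfap4 (-0.73, SE 0.10) and Postn (-0.60, SE 0.08). Bcl6, a transcriptional repressor, stood at 11.7 ± 1.0 FPKM in knockout and 21.02 ± 1.79 FPKM in control pads (SD, n = 3). The 3 knockout and 3 control values did not overlap for 14.3% of genes, against an average of 10% over all splits of the mice. Shares in the other splits were not computed. Leaving out control mouse M10 gave 1 called gene, and leaving out any other mouse gave 0.

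Inguinal fat of knockout mice had far less Mmd2 and Prtn3 transcript than control. Mmd2 (ENSMUSG00000039533, chromosome 5, 142562365 to 142608800), which encodes a membrane protein of the progestin and adipoQ receptor family, was 1.95 ± 0.09 FPKM in knockout and 55.1 ± 18.9 FPKM in control pads (SD, n = 3; log2 fold change -4.44, SE 0.27, limma adjusted p = 0.0220). Prtn3 (ENSMUSG00000057729, chromosome 10, 79874476 to 79883174), the serine protease proteinase 3 known from neutrophil granules, was 4.79 ± 1.04 and 57.3 ± 12.9 FPKM (SD, n = 3; log2 fold change -3.44, SE 0.21, limma adjusted p = 0.0220). The third called gene, the pseudogene Gm12725, lies outside the naming rule and was named after its values were seen (4.52 against 13.2 FPKM, limma adjusted p = 0.0341). Of 13621 genes tested these 3 were called, 0 higher and 3 lower. An unadjusted p under 0.05 was reached by 2024 genes, of which 1576 were lower, and by 3330 genes when M6, M10 and M12 were set against the other mice. Those mice had the highest inguinal B cell list means (4.41 to 4.98), but M5 stood close to them at 4.25.

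De novo lipogenesis genes rose in inguinal fat (18 of 21 members higher, median log2 fold change 0.82, camera adjusted p = 6.32e-15, adjusted p = 0.622 with an estimated correlation). Among them 14 rose and 1 fell when adjusted over the list alone. Acss2, which makes acetyl-CoA from acetate, was 169 FPKM in knockout and 55.6 FPKM in control pads (1.63, SE 0.22). Acly, Me1 and Fasn differed by 1.53 (SE 0.23), 1.49 (SE 0.27) and 1.35 (SE 0.26). Cholesterol synthesis genes were called upward with a small median of 0.07 (camera adjusted p = 1.50e-04, adjusted p = 0.622 with an estimated correlation). Fdps, Lss and Nsdhl were the 3 members that passed when adjusted over the list alone (0.68, 0.81 and 0.74). Without control mouse M10 the list median was -0.08 and the call was lost. It stayed called without any other mouse, with medians from 0.04 without M9 to 0.23 without M7, and at 0.30 with the skeletal muscle list as a covariate. All 19 cell cycle genes were higher (median 0.62, camera adjusted p = 3.15e-13, adjusted p = 0.622 with an estimated correlation). Levels were low, such as 2.08 against 1.02 FPKM for Cdk1, the member that passed when adjusted over the list alone. The list stayed called with a median of 0.41 without knockout mouse M12, 0.40 at a mean FPKM of at least 2 and 0.31 with the skeletal muscle list as a covariate, and its pad means overlapped between genotypes. The adipocyte identity list was not called (11 of 23 members higher, median -0.03, camera adjusted p = 0.257), and camera's direction was upward where its median and mean were negative. The fry mixed test called it (adjusted p = 0.0224). Its member Cfd, which encodes adipsin, was 4382 FPKM in knockout and 11390 FPKM in control pads (-1.40, SE 0.33, limma adjusted p = 0.173). Nnat differed by -1.87 (SE 0.29, limma adjusted p = 0.129) and was the 1 member that passed when adjusted over the list alone.

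Macrophage genes fell in inguinal fat, with 18 of 18 members lower (median -0.99, camera adjusted p = 2.52e-06, adjusted p = 0.622 with an estimated correlation) and 10 passing when adjusted over the list alone. Cd14 and Mrc1 differed by -1.01 (SE 0.19) and -1.06 (SE 0.25). Extracellular matrix genes fell (24 of 26 members lower, median -0.44, camera adjusted p = 4.39e-07, adjusted p = 0.622 with an estimated correlation), and 14 passed when adjusted over the list alone. Col1a2 and Fn1 stood at -0.70 (SE 0.11) and -0.81 (SE 0.13), and Thbs1 was 1.35 FPKM in knockout and 35.6 FPKM in control pads. All 20 endoplasmic reticulum and integrated stress genes were lower (median -0.37, camera adjusted p = 8.85e-06, adjusted p = 0.622 with an estimated correlation). Of these, 9 passed when adjusted over the list alone, among them Atf3 (-0.99, SE 0.16) and Sesn2 (-0.89, SE 0.17). Neutrophil and mast cell genes fell (9 of 10 members lower, median -0.68, camera adjusted p = 0.0122, adjusted p = 0.622 with an estimated correlation). The 5 members that passed when adjusted over the list alone included the mast cell protease genes Mcpt4 (-0.72, SE 0.17) and Cma1 (-0.76, SE 0.20) and the neutrophil gene Retnlg (-1.54, SE 0.39). Red blood cell genes were all lower (7 of 7, median -1.67, camera adjusted p = 7.75e-04, adjusted p = 0.622 with an estimated correlation), and 7 passed when adjusted over the list alone. Control mouse M7 lay near the knockout mice, with a list mean of 5.92 against 5.49 to 5.62 in knockouts. Controls M6 and M10 stood at 7.90 and 7.72. All 20 interferon-stimulated genes were lower as well (median -0.55, camera adjusted p = 0.0122, adjusted p = 0.694 with an estimated correlation), and 0 passed when adjusted over the list alone. That call was lost without control mouse M6 (median -0.26) and without knockout mouse M9 (median -0.37). The female reproductive tract list, with 4 measured members, fell (median -1.26, camera adjusted p = 0.0122, adjusted p = 0.622 with an estimated correlation). Its 2 members that passed when adjusted over the list alone encode hormone receptors. Oxtr, the oxytocin receptor, was 14.3 FPKM in knockout and 137 FPKM in control pads (-3.06, SE 0.39), and Pgr, the progesterone receptor, was 0.08 and 2.03 FPKM. The skeletal muscle list was called lower in the same pads (median -2.10).

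The inguinal lists called numbered 19 of 40 tested, 10 higher and 9 lower, and their adjusted p with an estimated correlation lay between 0.622 and 0.694. Thermogenic, oxidative phosphorylation, fatty acid oxidation, lipolysis, branched-chain amino acid, mitochondrial and circadian lists were also called upward, with medians of 0.29 or less, and inflammatory and skeletal muscle lists downward. Medians were only 0.004 for circadian (9 members higher and 9 lower), 0.04 for branched-chain and 0.05 for mitochondrial genes. Camera sets a list against all genes, whose median was -0.10, so these 3 calls do not by themselves show a rise of the members. Without control mouse M6, 10 of the 19 list calls were kept, 7 were lost in the same direction and 2 were lost with camera's direction reversed, with oxidative phosphorylation and branched-chain medians of -0.07 and -0.05. Medians of the fatty acid oxidation, mitochondrial and circadian lists were also negative there. Known FoxO target genes were not called in either depot (median -0.19 in inguinal and -0.01 in gonadal fat, camera adjusted p = 0.170 and 0.779). The fry mixed test, which asks whether members change in either direction, called that list in gonadal fat (adjusted p = 0.00705, against 0.0531 in inguinal fat), where Pck1 rose and Bcl6 fell when adjusted over the list alone. With 6 libraries per group counted as replicates, 486 genes were called higher and 1703 lower, and the authors' deposited table lists 1025 higher and 1195 lower. On rebuilt read counts, edgeR called 2 genes and DESeq2 657. Leaving out control mouse M7 gave 78 called genes, and leaving out any of the other 5 mice gave 0. Mmd2 and Prtn3 then had limma adjusted p of up to 0.162, with log2 fold changes of -4.23 or lower and -3.30 or lower. Array weights gave 4475 calls, all groups in a joint fit 106, and the skeletal muscle list as a covariate 0, with 1548 genes at an unadjusted p under 0.05. The 3 knockout and 3 control values did not overlap for 22.5% of genes, against an average of 10% over all splits of the mice. Shares in the other splits were not computed, so this excess alone is no evidence of a genotype effect. Median-ratio scaling moved the median of all genes from -0.10 to 0.01.

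**Figure D2:**
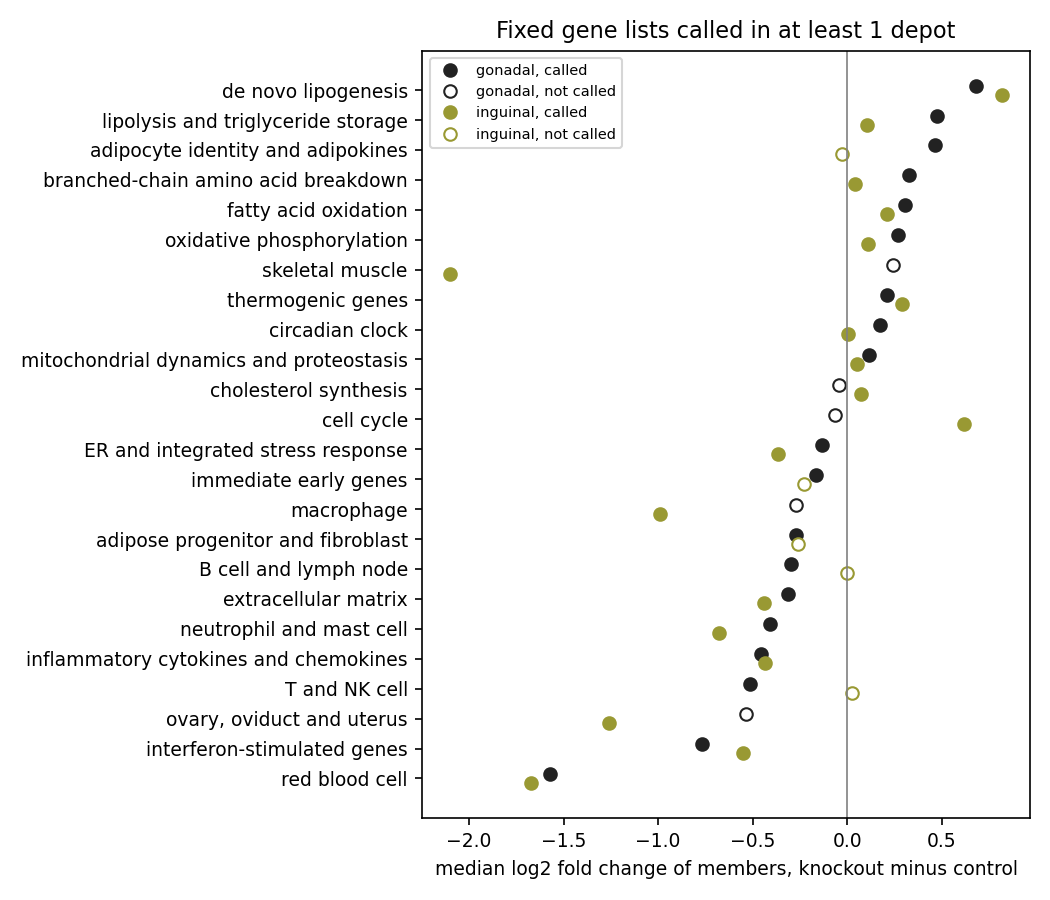
Median log2 fold change (knockout minus control, 3 mice per group) of the members of each fixed gene list called in at least 1 depot. Black points are gonadal and olive points inguinal fat, filled where limma camera with a preset correlation called the list; de novo lipogenesis lies at 0.68 and 0.82, and red blood cell genes at -1.57 and -1.67.

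**Figure D3:**
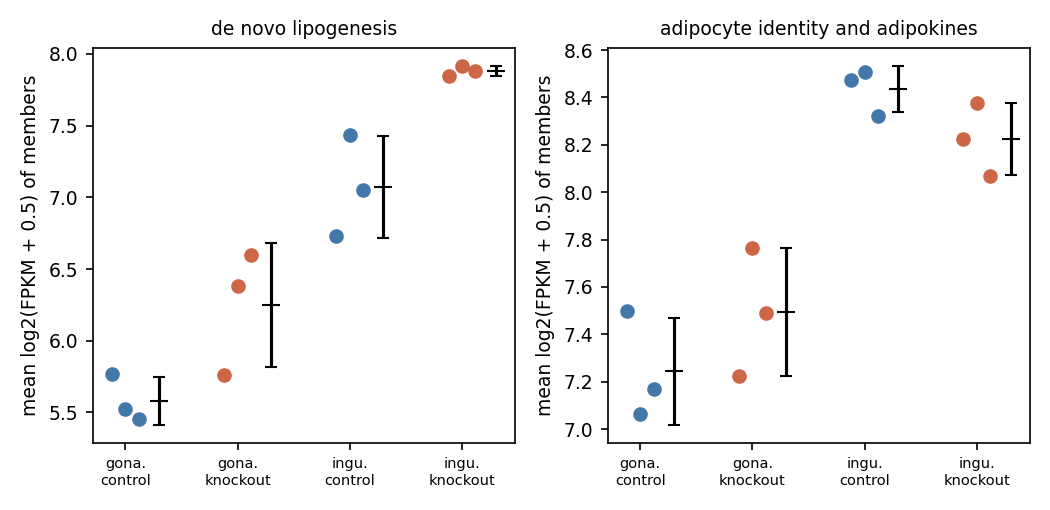
Mean log2(FPKM + 0.5) over the members of the lipogenesis list (left) and the adipocyte identity list (right) for each mouse, with control mice in blue and knockout mice in orange; bars show mean ± SD of 3 mice, and the vertical axes differ and do not start at 0. The lipogenic means of the 3 inguinal knockout pads lie between 7.85 and 7.92, above the 3 controls at 6.73 to 7.44, while the gonadal knockout means (5.76 to 6.60) overlap the controls (5.45 to 5.77).

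Pads differed in transcripts of other tissues, and the marker genes given here were chosen after their values were seen. Epididymal transcripts such as Crisp1 and Spink8 reached 705 and 892 FPKM in gonadal pads. Male tract genes exceeded 100 FPKM in the gonadal pads of knockout mouse M12 and control mice M6 and M10, with 8, 2 and 4 genes. In the other gonadal pads the highest male tract gene was at 1.04 FPKM, and the list was not called (6 of 9 members higher, camera adjusted p = 0.437). Cd79a, a B cell gene, was 1.26 and 1.503 FPKM in the inguinal pads of control mouse M7 and knockout mouse M9. It was 69.0 to 115 FPKM in the other inguinal pads, and the B cell list was not called there (camera adjusted p = 0.190). In gonadal fat that list was called lower (median -0.30, camera adjusted p = 0.0307, adjusted p = 0.764 with an estimated correlation). That call was kept in 6 of 10 alternatives fixed in advance. It was lost without knockout mice M12 (median -0.18) and M5 (-0.29) and without control mouse M6 (-0.02), and without M7 the median was -0.53 and still called. In the pads with no epididymal transcripts, with 1 control mouse, the median was 0.27. The skeletal muscle list was called lower in inguinal knockout pads (14 of 14 members, median -2.10, camera adjusted p = 0.0411, adjusted p = 0.694 with an estimated correlation), with Acta1 ranging from 2.57 to 278 FPKM. However, 0 members passed when adjusted over the list alone, and the call was lost in 5 of 10 alternatives, 4 of them without a mouse: M12 (median -0.95), M7 (-1.61), M6 (-1.66) or M5 (-2.28). Without M9 the median was -3.22 and still called. Pads of the genotypes overlapped, with list means of 3.90 in knockout mouse M9 and 2.41 in control mouse M10. These genes were not called in gonadal fat (median 0.24, camera adjusted p = 0.0949). Without the gonadal pads of M6, M10 and M12, limma called 0 genes, with 559 at an unadjusted p under 0.05. That fit holds 1 control mouse, assumed to vary like the others. Without the inguinal pads of M7 and M9 it called 31 inguinal genes, 3 higher and 28 lower.

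**Figure D4:**
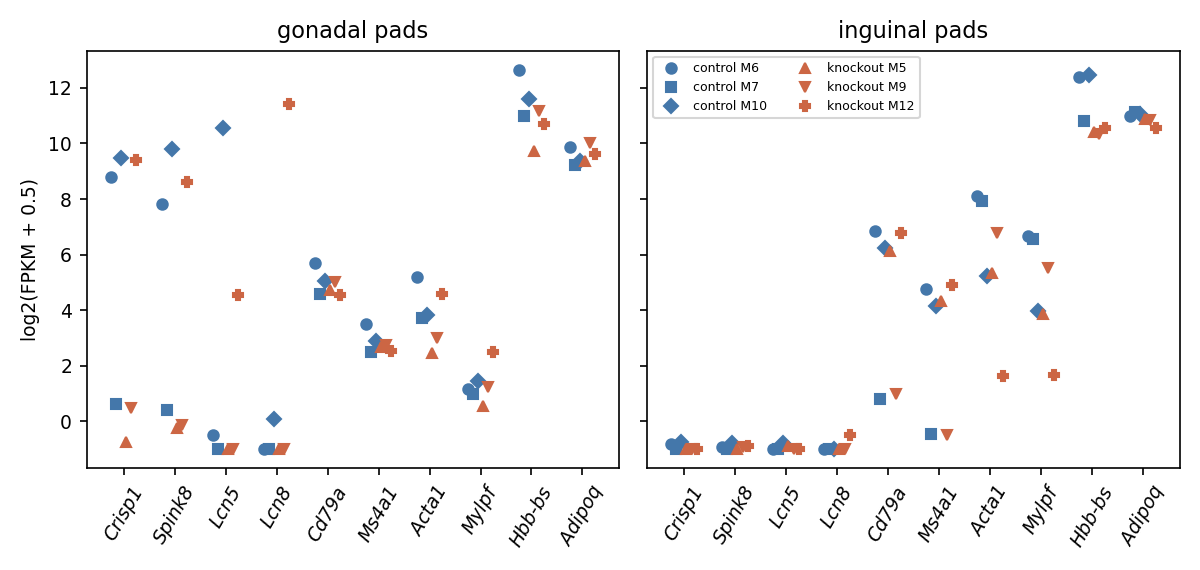
Level of marker genes in the gonadal (left) and inguinal (right) pad of each mouse as log2(FPKM + 0.5), with control mice in blue and knockout mice in orange and a symbol for each mouse. Epididymal genes (Crisp1, Spink8, Lcn5, Lcn8) are high in some gonadal pads of each genotype, B cell genes (Cd79a, Ms4a1) are low in the inguinal pads of M7 and M9, and muscle genes (Acta1, Mylpf) vary between inguinal pads.

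Whether the knockout acted differently in the 2 depots was tested with the interaction of genotype and depot. At list level, cell cycle genes had the smallest camera p: the gonadal effect lay below the inguinal effect for 22 of 22 members (median difference -0.63, camera adjusted p = 1.10e-17, adjusted p = 0.810 with an estimated correlation). Macrophage genes lay the other way for 20 of 20 members (median difference 0.65, camera adjusted p = 2.43e-04, adjusted p = 0.810 with an estimated correlation), and the adipocyte identity list had a median difference of 0.50 (camera adjusted p = 4.56e-04, adjusted p = 0.810 with an estimated correlation). Fry called 0 lists in the interaction, directional or mixed. Foxo1 itself differed by 0.68 (SE 0.38) between depots. No gene was called (limma, 14577 genes tested, 725 at an unadjusted p under 0.05), edgeR called 0 and DESeq2 12. With 6 libraries per group counted as replicates, 265 genes were called. The smallest p values had limma adjusted p of 0.619 or more. They belonged to Acot11, an acyl-CoA thioesterase gene (-2.03, SE 0.33), Cdkn2c (1.07, SE 0.18), Haus7 (0.65, SE 0.11), Slc38a6 (0.68, SE 0.13) and Efcab4a (0.66, SE 0.12), followed by Ppp2r3d (0.56, SE 0.11), Slc38a10 (-0.52, SE 0.10), Neat1 (0.99, SE 0.20), Col5a3 (0.95, SE 0.20) and Dleu2 (0.83, SE 0.18).

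Fold changes of the depots correlated across the 13201 genes tested in both (Pearson r = 0.49, Spearman rho = 0.43), and 65.9% of genes had the same sign. Genes are not independent replicates, and the same mice gave both pads. Bcl6 was lower in inguinal as in gonadal fat (7.28 against 27.1 FPKM, -1.87, SE 0.40, limma adjusted p = 0.160). No gene was called in both depots, and the one-sided Fisher exact test per direction gave p = 1 on 0 and 3 calls. With 0 gonadal calls that outcome was fixed, so the test says nothing about sharing between depots. With 6 libraries per group counted as replicates, 153 genes were called higher in both depots against 19.4 expected from independent lists, and 232 lower against 67.9.

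Control mice set the baseline against which these effects stand. Gonadal control fat had far more transcript of macrophage and inflammatory genes than inguinal control fat: Saa3, which encodes an acute-phase protein, was 2614 ± 1138 and 1.90 ± 0.91 FPKM (SD, n = 3), and Arg1 was 938 ± 421 and 0.35 ± 0.05 FPKM (SD, n = 3). Spp1, Slpi and Mmp12 were higher by 8.92 (SE 0.46), 7.71 (SE 0.47) and 7.22 (SE 0.54) on the log2 scale, with limma adjusted p of 5.65e-04 or less. Inguinal fat had more of the thermogenic genes Cidea (log2 difference -6.56, SE 0.56) and Ucp1 (-5.40, SE 0.57) and the muscle genes Tnnt3 (-6.02, SE 0.76) and Pvalb (-5.91, SE 0.86). Among depot developmental genes, Wt1, Tcf21, Gata5 and Upk3b were higher in gonadal fat by 5.63, 3.29, 3.03 and 7.01. Tbx15, Shox2 and Hoxc10 were lower at -3.72, -3.81 and -3.76, all past the threshold. Gata6 and Nr2f1 were also higher in gonadal fat (2.42 and 0.67), En1 and Hoxc9 lower (-1.48 and -1.62), and Sfrp2, listed as inguinal, was higher in gonadal fat (2.40). Hoxb6 and Hoxd9 differed by 1.13 (SE 0.58) and 0.66 (SE 0.33) and did not pass. Nr2f1 lost its call without any 1 of the control mice and under quantile normalization, and Hoxb6 gained it without M7 (1.83, limma adjusted p = 0.00565).

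Macrophage genes (18 of 20 members) and lysosome genes (20 of 23) were called higher in gonadal control fat over all genes tested. Their list medians were 3.09 and 1.17 (camera adjusted p = 3.19e-08 and 1.55e-07, each with adjusted p = 0.345 with an estimated correlation). All 34 oxidative phosphorylation genes and 17 of 21 lipogenic genes were called lower (medians -1.18 and -1.80, camera adjusted p = 1.97e-18 and 1.59e-09, each with adjusted p = 0.345 with an estimated correlation). The adipocyte identity list was lower as well (17 of 23 members called lower and 1 higher, median -1.31, camera adjusted p = 1.59e-09, adjusted p = 0.345 with an estimated correlation). A smaller adipocyte share of the RNA and lower levels within adipocytes were therefore not told apart. Over all genes, limma called 3904 genes higher and 2106 lower in gonadal control fat (14505 genes tested), and 1534 in all without mouse M10. Counting 6 libraries per group as replicates gave 9100. The direction split moved with the scaling. Median-ratio scaling gave 3039 higher and 2874 lower, and quantile normalization 2622 and 3899. The median of all genes moved from 0.18 to 0.02 under median-ratio scaling.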

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

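The gene lists, camera within each depot, median-ratio scaling and the estimated correlation were fixed in advance. The other tests in this part were chosen after the results were seen. Camera on the interaction of genotype and depot called 13 gene lists at a preset correlation, and none with an estimated correlation. Fry called 0 lists in the interaction, directional or mixed. Camera sets a list against all genes, whose median difference was 0.08, so the small negative medians are partly relative to that shift. Values are the median of the gonadal minus the inguinal log2 effect. The difference was positive for skeletal muscle (2.4), macrophage (0.65), adipocyte identity (0.50), lipolysis and triglyceride storage (0.38), known FoxO targets (0.28) and branched-chain amino acid breakdown (0.25). It was negative for cell cycle (-0.63), epithelium and mammary gland (-0.52), T and NK cell (-0.50), interferon-stimulated (-0.23), de novo lipogenesis (-0.11), thermogenic (-0.094) and cholesterol synthesis genes (-0.089).

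Male tract transcripts in gonadal pads may come from epididymis dissected with the pad: 3 of 6 gonadal pads had at least 2 male tract genes above 100 FPKM, and none had a lone one. That count uses the genes by which these pads were picked out, so it restates the pattern and is no separate test of the source. Genotype as the source is argued against, since 1 knockout pad and control pads were affected. B cell transcripts low in some inguinal pads may mark pads without the lymph node: 16 of 17 T and NK cell genes, a list sharing no gene with the B cell list, had the same lowest pair of pads. By chance 1.13 would be expected of independent genes, which genes of the same cells are not. Fewer lymphocytes for another reason would give the same pattern, so the count cannot single out the lymph node. Genotype is argued against here too, since 1 pad of that pair was knockout.

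At the preset correlation the lipogenic list was called higher in knockout pads of each depot. With an estimated correlation it was called in neither (camera adjusted p = 0.578 in gonadal and 0.622 in inguinal fat). Knockout list means lay above all controls for 2 of 3 gonadal and 3 of 3 inguinal pads. A larger adipocyte share of the RNA is argued against in inguinal fat only as far as the adipocyte list measures that share. The lipogenic mean exceeded the adipocyte list mean by 1.02 more in knockout than control pads (95% interval 0.42 to 1.62), while the adipocyte list itself differed by -0.21. That list is not neutral, since the fry mixed test called it (adjusted p = 0.0224) with a median of -0.03. Macrophage and extracellular matrix lists also fell (medians -0.99 and -0.44), as a larger adipocyte share could give, so such a share is not excluded. In gonadal fat the same difference was 0.419 (95% interval -0.10 to 0.94), so a larger adipocyte share and a change within adipocytes cannot be told apart with 3 mice per group. Scaling between libraries is argued against, since the lipogenic median was 0.703 in gonadal and 0.936 in inguinal fat after median-ratio scaling. An effect of FoxO1 loss within adipocytes stays a hypothesis for inguinal fat; the exact permutation p of this difference was 0.1 in each depot, the smallest possible.

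With 3 mice against 3 there are 10 splits, too few for a share under 0.05. Each mixed split of the genotypes exchanges 1 knockout mouse for 1 control mouse, so it retains part of any genotype effect. The splits for the depot comparison regrouped the control pads and ignored which pads share an animal number. The real split gave 0 gonadal genes and the highest other split 45 (10 splits as large), 3 inguinal genes against 0 (1 split as large), 0 interaction genes against 55 (10 splits as large), 6010 genes between depots against 0 (1 split as large), 19 gonadal lists against 21 (3 splits as large) and 19 inguinal lists against 20 (3 splits as large). An unadjusted p under 0.05 was reached by 1291 gonadal genes in the real split and 2330 in the highest other, and by 2024 inguinal genes against 3330. The absolute lipogenic median was 0.68 in gonadal fat against 0.77 in the highest other split, and 0.82 against 0.61 in inguinal fat. With 6 libraries per group counted as replicates, the real split gave 1125 gonadal genes against 2871 (3 splits as large) and 2189 inguinal genes against 4216 (2 splits as large), so splits that mix the genotypes call as many genes and point to a structure of the mice. The split that called 4216 inguinal genes, and also 45 gonadal and 55 interaction genes, set M6, M10 and M12 against the others. Their gonadal pads held epididymal transcripts, while no inguinal pad had a male tract gene above 2.18 FPKM. Their inguinal pads had the highest B cell list means (4.98, 4.41 and 4.98, against 4.25 in M5, 0.44 in M7 and 0.43 in M9). In gonadal fat this split therefore followed the epididymal content of the pads and is not a neutral comparison. In inguinal fat the B cell means did not clearly divide the mice this way, since M5 lay close to M10. Skeletal muscle list means did not follow the split either (4.56 in M6 and 0.45 in M12). What lay behind the inguinal calls of this split was not tested. The correlation of fold changes between depots was 0.49 against 0.45 (1 split as large).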

How the results depend on the processing

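The fit with 6 libraries per group, the count tools, the covariates, the subsets of pads and the animal block were chosen after seeing the data. Counting 6 libraries per group as replicates gave 1125 gonadal, 2189 inguinal, 265 interaction and 9100 depot genes, 385 genes shared between depots, and called Foxo1 at -1.18 and -1.86; its count of mice as several samples makes its p too small. DESeq2 on rebuilt read counts gave 308, 657 and 12 genes for gonadal, inguinal and interaction, 92 shared, and called Foxo1 at -1.29 and -1.82, while edgeR gave 0, 2 and 0. Array weights, whose estimation stopped before convergence in some fits, gave 4475 inguinal and 10140 depot genes, and all groups in a joint fit gave 106 inguinal genes. For inguinal fat, the B cell list as a covariate gave 579 genes and called Foxo1 at -1.85, the skeletal muscle list as a covariate gave 0, and the pads with lymphocyte transcripts alone gave 31. Camera with the correlation estimated called 0 lists in each depot, as did fry's directional test, while fry's mixed test called 2 gonadal and 13 inguinal lists. Leaving out each mouse gave 0 to 1 gonadal, 0 to 78 inguinal, 0 interaction and 1534 to 5257 depot genes, and 13 to 22 lists in each depot; Foxo1 stayed between -1.34 and -0.97 in gonadal and -2.11 and -1.58 in inguinal fat. The cause was not tested, beyond fewer mice in these fits.

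The direction given by camera reversed for these lists, with medians in parentheses: B cell genes in gonadal fat (-0.0206 without control mouse M6, where the median kept its sign, and 0.267 in pads with no epididymal transcripts, with 1 control mouse), inguinal oxidative phosphorylation (-0.0655) and branched-chain amino acid breakdown (-0.0467) without M6, and inguinal skeletal muscle (0.0251 with its own list as a covariate, which removes it by construction). Medians of inguinal lists also changed sign, with the call lost, for cholesterol synthesis (-0.0847 without M10), fatty acid oxidation (-0.00286) and mitochondrial dynamics (-0.0176) without M6, and circadian genes (-0.0699 without M5, and negative without M6, without M9 and at a mean FPKM of at least 2). Median-ratio scaling raised small inguinal medians, such as oxidative phosphorylation to 0.232 and lipolysis to 0.226. The genes named by rank or depot were not tallied under the covariates, the subsets of pads or DESeq2. Of the values tallied for them none reversed: 667 stayed on their side of the threshold, 14 lost the call (Mmd2 and Prtn3 without each mouse but M7, and Nr2f1) and 25 gained it. With the skeletal muscle list as a covariate no inguinal gene was called by limma, Mmd2 and Prtn3 included. Pseudocounts, filters, median-ratio scaling, quantile normalization and the robust trend left each total count of genes within 1.5 times, but quantile normalization moved the genes lower in gonadal control fat from 2106 to 3899.

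With the animal number as a replicate block, 5092 genes differed between depots, against 6010 without it, and 0 in the interaction; no named gene of these comparisons changed its side of the threshold. No paired analysis was possible for the knockout comparisons because the columns carry no replicate numbers shared by knockout and control mice. Xist as a covariate was not run, since Xist stayed at 0.06 FPKM or less in all pads. Depth may limit genes below a few FPKM, such as the cell cycle list. This was not tested.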

Other observations

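The haemoglobin gene Hbb-bs ranged from 840 to 6430 FPKM in gonadal and from 1290 to 5700 FPKM in inguinal pads. The clock genes of inguinal fat moved apart, with Nr1d1 and Bhlhe40 higher in knockout pads by 0.47 (SE 0.07) and 1.12 (SE 0.25) and Nfil3 lower at -0.87 (SE 0.18); these 3 members passed when adjusted over the list alone. The chemokine genes Ccl6 and Ccl9 stood at -1.80 (SE 0.34) and -1.82 (SE 0.35) in inguinal fat, the 2 members of their list that passed when adjusted over the list alone. Gpx3, an extracellular glutathione peroxidase gene, was 235 FPKM in inguinal knockout and 1521 FPKM in control pads (log2 fold change -2.68, SE 0.22, limma adjusted p = 0.0570). Its list of oxidative stress defence genes was not called by camera (adjusted p = 0.232) but was by the fry mixed test (adjusted p = 0.00695), with 3 members lower when adjusted over the list alone. In gonadal fat, Retn, which encodes resistin, was 671 FPKM in knockout and 376 FPKM in control pads, and Oxtr was 12.1 and 73.85 FPKM.

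Of the genes listed as changed in the authors' deposited tables, 1717 gonadal and 2064 inguinal genes were tested here, and 100% and 99.9% had the same direction in the 3-mouse fit. They were chosen as changed on the same libraries, so this agreement was built in and is no separate support. Of them 1163 and 1410 had an unadjusted limma p under 0.05, and for 76.2% and 76.8% the values of the 3 knockout and 3 control mice did not overlap, against 10% by chance for genes not chosen on these samples.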
